A study of Homo sapiens with 14 samples.

How the data were processed

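The series holds 14 samples of human CD14+ monocytes: 8 H3K27ac libraries, 4 IRF1 libraries and 2 input libraries. No processed file came with the input libraries, and they were not analysed here. Conditions and replicate numbers were taken from the labels. The 12 peak lists have no header, so what each column holds was read from its values.

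Per the submitters' processing notes, the reads came through CASAVA 1.7 and Bowtie, whose version is not given in the sources used here, with build hg19. The peak caller, its threshold and its use of the input libraries are likewise not given in the sources used here. The authors deposited 1 list per library, so replicates had not been pooled and could be compared. Each line of the deposited lists gives a start, an end, a score that is always negative, a further positive score by the authors, the position of the highest point and the height there. The deposited height is a signal in whole units, reaches at most 340 in the H3K27ac lists, and is not normalized as far as the values show. What the 2 deposited scores are relative to is not given in the sources used here, so they served only to rank or filter peaks within a list.

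The weakest negative score was -20 in the replicate 1 H3K27ac lists, -15 in the replicate 2 lists and -10 in the IRF1 lists. Each list thus ended at a limit that differed between replicate numbers, which changes how many weak peaks a list holds. At a common limit of -20 the replicate 2 lists held 61705, 50977, 57871 and 52065 peaks in control, IFN-γ, LPS and IFN-γ plus LPS cells, still above the 32253 to 40541 of replicate 1. The median height of H3K27ac peaks with scores between -21 and -20 was 28 to 35 in replicate 1 and 51 to 56 in replicate 2. Read depth is unknown, so no counting error can be given for a peak's height. Where a list was short or its library shallow, a missing peak means that none passed the authors' limit, not that the site was bare.

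Only autosomes and chromosome X were used; sequences outside these were left out before any count. Coordinates are printed as the lists give them, and whether their starts count from 0 or from 1 is not given in the sources used here. The gene table at hand belongs to the GRCh38.p14 assembly and the peaks to hg19, so positions were not assigned to genes. The planned shares of gene lists, the check for marker genes of other blood cells and the search for IRF sequence motifs were therefore not run.

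Peaks of the 8 H3K27ac lists that overlapped by at least 1 bp were merged into union regions. A library counted as having a peak at a region when any of its peaks overlapped it. Regions gained or lost in both replicates were counted for IFN-γ, LPS and the combination against control cells, for LPS in primed cells (combination against IFN-γ) and for priming in LPS-stimulated cells (combination against LPS). Regions with peaks in both combination libraries and in no other library were counted as well, which makes 11 counts. For the chance count, the pattern of each replicate over the 4 conditions was permuted between regions with the same number of peaks in replicate 1, the same number in replicate 2 and the same of 3 width classes. The one-sided p is the share of 100000 draws with at least as many regions, adjusted by the Benjamini-Hochberg method over the 11 counts. This test uses regions as its units, and neighbouring regions are not independent, so 24 matchings of whole lists across replicates were tested as well. Peak number and covered length were compared on the log2 scale by exact two-sided permutation of 4 against 4 libraries (70 permutations, smallest p 0.0286). Overlaps between gains that share the control libraries were set against 1000 permutations of the same kind and against the overlap of independent lists.

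The counting was tested on simulated data. In 100 runs per comparison, 200 regions of 114637 were given a change in both replicates of otherwise permuted lists. All planted regions were recovered, which the planting itself fixes. The count exceeded chance in 100 runs for IFN-γ, 98 for LPS, 89 for the combination, 100 for LPS in primed cells and 100 for priming. Of 100 runs with no planted change, 3, 4, 6, 8 and 8 were called in the same order. All runs were drawn by the permutation that the test itself uses. It removes the dependence between neighbouring regions, so the runs do not check the test against such dependence. With planted changes the mean excess over chance was 101, 71.5, 56.7, 89.5 and 93.5 regions, so in these runs the excess understated the number of planted regions.

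IRF1 peaks were called shared when they overlapped by at least 1 bp, and described without a test because each condition had 1 library. The share of each H3K27ac class with an IRF1 peak was set against 10000 random sets of union regions drawn to match the class in size and in 10 classes of width. Sets that also match the presence or absence of a peak in each H3K27ac library of the IRF1 list's condition, and sets drawn for classes from 1 replicate alone, were added after the data were seen. The share of IRF1 peaks inside H3K27ac peaks of each library was compared by exact two-sided permutation within replicate number (36 permutations, smallest p 0.0556) and over all libraries, with Benjamini-Hochberg adjustment over 18 tests. That last comparison was added after the lists had been read. Intervals of shares are Wilson 95% intervals.

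The regions named are the 5 widest of each class, and the IRF1 peaks named come from the 10 with the highest authors' score in each list. These rules, the groups, the tests other than the last and the alternatives were set before the data were examined, apart from those named as added. The rules were written for the genes nearest to these positions and are applied here to the positions themselves. Regions listed with chromosome 10 left out were chosen after their values were seen. The alternatives were the stronger 50% of each list, equal list lengths, a stricter overlap, joined peaks, only wide peaks, an untransformed scale, another similarity index, other permutation schemes and each replicate left out. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.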

Results

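Chromatin immunoprecipitation with sequencing was used to map an active chromatin mark and a transcription factor in human CD14+ monocytes purified from the blood of healthy donors. The cells were kept with 10 ng/ml M-CSF, a growth factor that supports monocyte survival. They were left as controls, exposed to 100 U/ml IFN-γ for 24 hours, stimulated with 50 ng/ml LPS, or exposed to IFN-γ and then stimulated with LPS. IFN-γ is a macrophage-activating cytokine and LPS is a bacterial cell wall component sensed through a Toll-like receptor. H3K27ac, a histone acetylation found at active promoters and enhancers, was mapped after 3 hours of LPS in 8 libraries, replicates 1 and 2 of each of the 4 conditions. IRF1, a transcription factor induced by IFN-γ, was mapped after 6 hours of LPS in 4 libraries, 1 per condition. The series title names its question, whether priming of regulatory DNA accounts for stronger cytokine gene activation when both signals are combined.

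The H3K27ac lists differed more by replicate number than by condition. The replicate 1 lists held 32253 peaks in control cells, 36149 after IFN-γ, 37289 after LPS and 40541 after both, and covered 27.1, 29.6, 32.2 and 34.7 Mb. The replicate 2 lists held 80384, 68252, 76085 and 71237 peaks in the same order of conditions, and covered 76.3, 78.2, 66.3 and 75.8 Mb. The mean number of peaks was 56319 ± 34034 in control cells, 52201 ± 22700 after IFN-γ, 56687 ± 27433 after LPS and 55889 ± 21705 after both (SD, n = 2). The mean length covered was 51.7 ± 34.8, 53.9 ± 34.4, 49.3 ± 24.1 and 55.3 ± 29.0 Mb (SD, n = 2). The plot of peaks per library shows these values beside the IRF1 lists. Read depth is unknown, so part of the difference between replicate numbers cannot be set against depth.

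**Figure D1:**
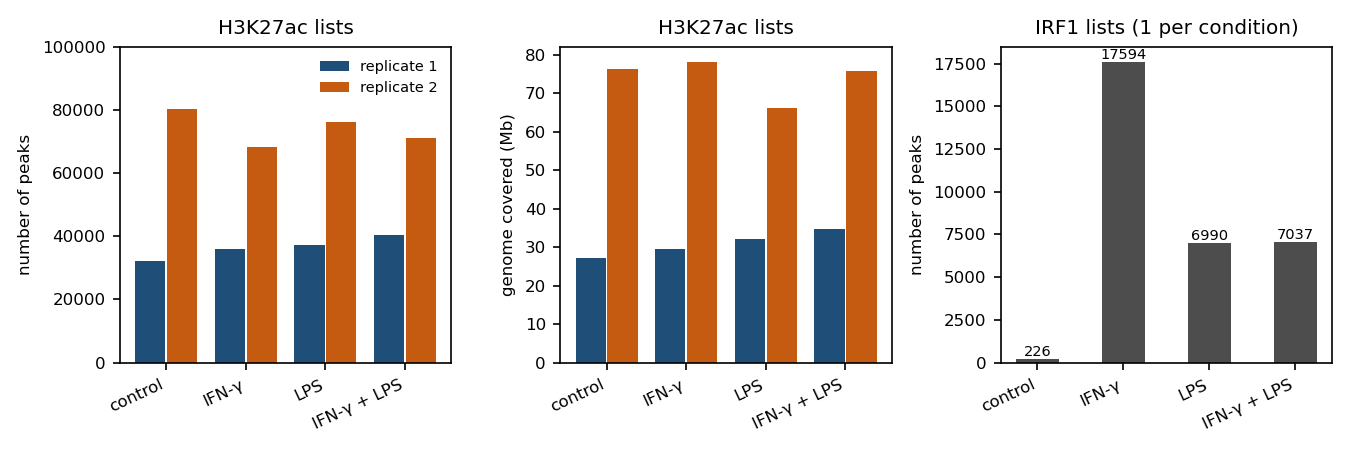
Number of H3K27ac peaks (left), genome covered by H3K27ac peaks in Mb (middle) and number of IRF1 peaks (right) in each deposited list, by condition; bars are single libraries, blue for replicate 1 and orange for replicate 2. All 4 replicate 2 bars, from 68252 to 80384 peaks, stand above all 4 replicate 1 bars, from 32253 to 40541, and the IRF1 bars run from 226 in control cells to 17594 after IFN-γ.

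Neither signal changed the total extent of H3K27ac by more than the spread between libraries, which here takes in the difference between replicate numbers. Across the 4 libraries with and the 4 without IFN-γ, the log2 difference was -0.01 for peak number (exact permutation test, two-sided, p = 0.943) and 0.11 for covered length (exact permutation test, p = 0.629). For LPS the log2 differences were 0.09 (exact permutation test, p = 0.686) and 0.06 (exact permutation test, p = 0.829). Of these 4 differences, 3 turned in direction between replicate numbers. For peak number IFN-γ gave 0.14 in replicate 1 and -0.17 in replicate 2, LPS gave 0.19 and -0.01, and for covered length LPS gave 0.24 and -0.12. The IFN-γ difference in covered length did not turn, with 0.12 in replicate 1 and 0.11 in replicate 2, and was positive in all 4 pairs of libraries (0.03 to 0.19). Its exact permutation p within replicate number was 0.278. The pair with 0.19 and the LPS difference of -0.12 use the replicate 2 LPS list, which had no chromosome 10 peak beyond 3.81 Mb. Without chromosome 10 covered length differed by 0.10 for IFN-γ (exact permutation test, p = 0.629) and 0.07 for LPS (exact permutation test, p = 0.743).

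Merging all H3K27ac peaks gave 114637 union regions with a median width of 480 bp. A peak was present in all 8 libraries at 14100 regions, whose median width was 2280 bp, and in 1 library only at 49084 regions (42.8%). Both replicates of at least 1 condition had a peak at 31749 regions. Base-pair Jaccard indices, the shared length divided by the length covered by either list, were 0.477 to 0.635 within replicate 1 and 0.464 to 0.603 within replicate 2. They were 0.336 to 0.416 between replicates of the same condition and 0.285 to 0.387 between replicates of different conditions. The mean for same-condition pairs, 0.372, was higher than for every other way of pairing the lists across replicates, of which the highest was 0.363 (exact permutation test over 24 matchings, one-sided, p = 0.0417, the smallest possible). The IFN-γ lists taken singly did not follow this mean. IFN-γ replicate 1 had an index of 0.336 with IFN-γ replicate 2 and 0.350 with LPS replicate 2. IFN-γ replicate 2 had 0.352 with replicate 1 of both signals. Control cells (0.338), LPS (0.416) and both signals (0.398) had their highest index across replicates with their own condition. The region patterns themselves gave a mean correlation of 0.116 between replicates of one condition after each replicate's own mean was subtracted, against 0.0730 for the highest other matching (exact permutation test, p = 0.0417). In these patterns every condition correlated most with itself, IFN-γ least so, at 0.0655.

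In what follows a region was called gained when both libraries of a condition had a peak there and neither library of the comparison condition did, and lost in the reverse case. The count was compared with the count expected if the replicates had changed independently of each other, given how many peaks each region had in each replicate. A single region cannot be tested, because 2 libraries against 2 allow no permutation p below 0.333. Positions are on build hg19. The p-values of these counts come from permuting patterns between regions, which are not independent of their neighbours, and do not measure the spread between samples. The exact permutation tests of whole lists across replicates above reached p = 0.0417, the smallest possible. They take all conditions together and do not test any single condition or count. The p-values of tests over libraries measure only the spread between these samples, which may be technical, since the labels do not say that the replicates came from separate donors.

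The first comparison asked what IFN-γ alone did to H3K27ac. After 24 hours of IFN-γ, 864 regions with a total width of 1.87 Mb were gained and 612 with a total width of 0.782 Mb were lost. Total widths, here and in the later comparisons, are those of union regions, which were merged from the lists of all conditions. They can exceed the length in peaks of the compared libraries and do not measure the length of acetylation gained or lost. The widest gained region lay on chromosome 1 from 1137537 to 1155950, where the IFN-γ libraries had peaks over 3283 bp in replicate 1 and 1108 bp in replicate 2 and the control libraries had none. The next lay on chromosome 8 from 39768861 to 39786003, with 4242 and 15205 bp in peaks, and on chromosome 16 from 11396882 to 11411097, with 10291 and 14215 bp. The fourth and the fifth widest were on chromosome 7 from 148271972 to 148284551 and on chromosome 19 from 40041624 to 40050920. Among the lost regions the widest lay on chromosome 1 from 25309477 to 25319959, where the control libraries had peaks over 2888 and 10482 bp and the IFN-γ libraries none. The other 4 were on chromosome 5 from 177745857 to 177753271, chromosome 8 from 131073752 to 131080057, chromosome 2 from 232031434 to 232036646 and chromosome 15 from 39679428 to 39684518.

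Both IFN-γ counts exceeded chance. The gains numbered 1.66 times the 522 expected by chance (95% of draws 493 to 551), and the losses 1.88 times the 326 expected (299 to 354), each with p = 1e-05 in a one-sided permutation test over regions, the smallest that 100000 draws can give, and 1e-05 after Benjamini-Hochberg adjustment over the 11 counts. With all 8 libraries permuted without regard to replicate number, 732 gains and 506 losses were expected (permutation p = 0.001 for each, the smallest that 1000 draws can give). Replicate 1 alone gave 5689 gains and 3467 losses and replicate 2 alone 17262 and 26024. With lists shortened to 32253 peaks each the counts were 1524 and 1155, and with the stronger 50% of each list they were 396 and 238.

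**Figure D2:**
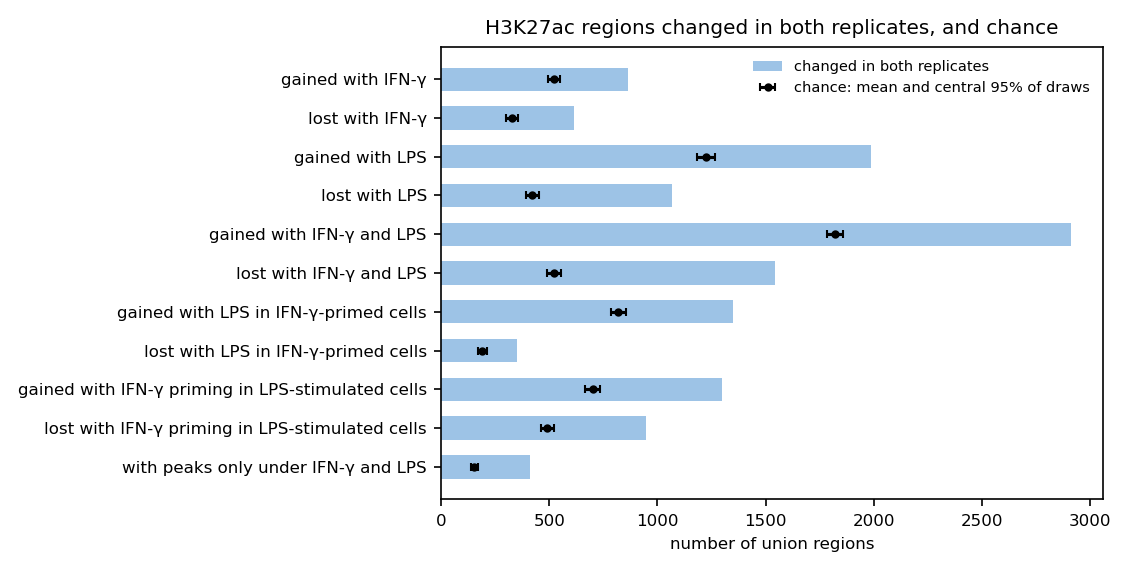
Number of H3K27ac union regions changed in both replicates for each of the 11 comparisons (bars) with the mean and the central 95% of 100000 chance draws (points and whiskers); the horizontal axis counts regions. Every bar ends beyond its chance interval, from 349 regions against a chance mean of 190 for losses with LPS in primed cells to 2915 against 1822 for gains with both signals.

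The second comparison asked what LPS did in cells that had seen no IFN-γ. After 3 hours of LPS, 1986 regions with a total width of 3.10 Mb were gained and 1068 with a total width of 1.49 Mb were lost. The widest gained regions included the pair on chromosomes 1 and 8 that were also gained with IFN-γ. On chromosome 1 from 1137537 to 1155950 the LPS libraries had 15176 and 14008 bp in peaks, more than the IFN-γ libraries had. The others lay on chromosome 11 from 76391085 to 76405813, chromosome 8 from 39843311 to 39857951 and chromosome 20 from 48307401 to 48320970. On chromosome 20 the LPS libraries had 6387 and 10237 bp in peaks, and 3 IRF1 peaks of the LPS list fell in the region.

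The LPS gains numbered 1.62 times the 1224 expected by chance (1184 to 1264), and the losses 2.54 times the 420 expected (390 to 451), each with p = 1e-05 by the permutation test and 1e-05 after adjustment. Without regard to replicate number 865 gains and 529 losses were expected (permutation p = 0.001 for each). Replicate 1 alone gave 6985 gains and 3911 losses and replicate 2 alone 19675 and 28205. The stronger 50% of each list gave 835 gains and 453 losses, joining peaks up to 500 bp apart gave 1285 and 691, and equal list lengths gave 1945 losses.

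The replicate 2 LPS list stood apart on chromosome 10. It had 961 peaks there, all between 0.114 and 3.81 Mb, whereas the other 7 lists reached beyond 135 Mb. Chromosome 10 held 1.26% of that list against 4.41% to 4.66% of the other replicate 2 lists. No LPS gain lay on chromosome 10, and 172 of the 1068 LPS losses (16.1%) did, compared with 5.06% of all union regions. Of the 5 widest losses, 4 lay on chromosome 10 and are not described as LPS effects. Without chromosome 10, LPS losses numbered 896 against 311 by chance (permutation p = 1e-05) and LPS gains again 1986 against 1263 (permutation p = 1e-05). The widest loss in either case was on chromosome 11 from 10618334 to 10626469, where the control libraries had peaks over 3099 and 8135 bp and the LPS libraries none. The following 4 outside chromosome 10 were on chromosome 18 from 3721899 to 3727793, chromosome 13 from 49047839 to 49053698, chromosome 18 from 376067 to 381293 and chromosome 3 from 54999272 to 55004073.

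The combination of both signals was compared with control cells next. It gave the highest counts, 2915 regions gained and 1545 lost, with total widths of 5.10 and 2.45 Mb. The widest gains were those on chromosomes 1, 8, 11 and 16 already named. On chromosome 1 from 1137537 to 1155950 the combination libraries had 17883 and 16985 bp in peaks. On chromosome 16 from 11396882 to 11411097 they had 10145 and 13318 bp, close to the 10291 and 14215 bp after IFN-γ alone, while LPS alone gave no peak in replicate 1 and 1152 bp in replicate 2. The widest loss lay on chromosome 2 from 218702860 to 218718984, with 6539 and 16124 bp in peaks in control cells and none after both signals. A neighbouring region on chromosome 2 from 218772961 to 218780662 was lost as well, as were regions on chromosome 1 from 25309477 to 25319959, chromosome 11 from 10618334 to 10626469 and chromosome 1 from 18483654 to 18491233.

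Gains with both signals numbered 1.60 times the 1822 expected by chance (1783 to 1860), and losses 2.97 times the 520 expected (488 to 552), each with p = 1e-05 by the permutation test and 1e-05 after adjustment. Without regard to replicate number 1159.8 gains and 449 losses were expected (permutation p = 0.001 for each). Replicate 1 alone gave 9184 gains and 4182 losses and replicate 2 alone 23571 and 31699. The stronger 50% of each list gave 1311 gains and 619 losses, and equal list lengths gave 2427 losses.

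Gains with 1 signal were often present after both. Of the 864 IFN-γ gains, 558 (64.6%) were also gained with the combination, and of the 1986 LPS gains, 870 (43.8%) were. IFN-γ and LPS gains had 211 regions in common, which is 24.4% of the former and 10.6% of the latter. Permuting the patterns of each replicate between regions, with the same control libraries on both sides, gave 328 (308 to 348), 553 (531 to 576) and 146 (135 to 157) shared regions. The observed overlaps lay above all 3 ranges. The permutation also gave fewer gains, however, on average 522 with IFN-γ, 1224 with LPS and 1822 with both. Larger overlaps are partly given by more gains, so they do not show that gains were shared more often than by chance. Independent lists would share 22.0, 50.5 and 15.0 regions. There were too few control libraries to split, so part of the excess over independent lists may come from the shared controls. The permutation keeps these controls shared, so its counts already hold that part. No LPS gain was found on chromosome 10.

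Seen from the combination, 356 of its 2915 gains (12.2%) were also gained with IFN-γ only, 668 (22.9%) with LPS only, and 202 (6.93%) with each of the signals alone. The remaining 1689 (57.9%) were gained in both replicates with neither signal alone. At 409 of these (14.03% of all combination gains) no library outside the combination had any peak, 2.68 times the 152 expected by chance (136 to 169; permutation p = 1e-05, adjusted 1e-05) and above the 188 expected without regard to replicate number (permutation p = 0.001). Their median width was 720 bp, against 898 to 1841 bp for the other 10 groups of changed regions and 480 bp for all union regions. Regions with peaks in the combination libraries only are merged from fewer lists than other groups can be, which tends to make them narrower by construction. The widest was on chromosome 22 from 29105703 to 29113731, where the combination libraries had peaks over 1719 and 8028 bp. Others were on chromosome 7 from 93806090 to 93810353 and on chromosome 20 from 9387728 to 9391644. The 2 remaining regions of the widest 5 lay on chromosome 10, where the replicate 2 LPS list had no peak beyond 3.81 Mb, and the count without that chromosome was 381. Replicate 1 alone gave 3495 such regions and replicate 2 alone 10748, the stronger 50% of each list gave 131, and joining peaks up to 500 bp apart gave 223.

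The response to LPS in IFN-γ-primed cells was taken from the combination against IFN-γ alone. In primed cells 1348 regions were gained with LPS and 349 were lost, with total widths of 1.85 and 0.545 Mb. The widest gain was on chromosome 17 from 38712600 to 38722802, where the combination libraries had 3584 and 10202 bp in peaks, LPS alone gave none and 132 bp, and the IFN-γ and control libraries had none. A region on chromosome 12 from 24867923 to 24876140 was acetylated after LPS with or without priming, with 6412 and 7780 bp in peaks after LPS alone and 3500 and 7864 bp after both. Regions on chromosome 14 from 94836517 to 94845295, chromosome 22 from 29105703 to 29113731 and chromosome 12 from 92992140 to 92999730 completed the 5 widest. The widest losses were on chromosome 2 from 218702860 to 218718984, chromosome 7 from 36301523 to 36308640, chromosome 13 from 49047839 to 49053698, chromosome 1 from 23176238 to 23182082 and chromosome 5 from 177763917 to 177769638. At all 5 the IFN-γ libraries already had fewer base pairs in peaks than the control libraries of the same replicate number. On chromosome 2 they had 134 and 3462 bp against 6539 and 16124 bp, and on chromosome 5 they had 135 and 560 bp against 930 and 5721 bp. The widths thus overstate what was lost with LPS in primed cells.

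Gains numbered 1.65 times the 818 expected by chance (783 to 854) and losses 1.84 times the 190 expected (168 to 212), each with p = 1e-05 by the permutation test and 1e-05 after adjustment. The call for losses depended on how chance was drawn. When all 8 libraries were permuted with no regard to replicate number, 602 losses were expected and the observed 349 no longer exceeded chance (permutation p = 1), while 1075 gains were expected (permutation p = 0.001). Replicate 1 alone gave 6238 gains and 3458 losses and replicate 2 alone 18588 and 17954, the stronger 50% of each list gave 533 and 177, joining peaks gave 818 gains, and equal list lengths gave 821 losses.

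The effect of IFN-γ priming was also read in LPS-stimulated cells, by comparing the combination with LPS alone. Priming was accompanied by 1300 gains and 949 losses, with total widths of 1.97 and 1.13 Mb. Of the gains, 187 (14.4%) lay on chromosome 10, where the replicate 2 LPS list had no peak beyond 3.81 Mb, and 2 of the losses did. Without that chromosome 1113 gains remained against 541 by chance and 947 losses against 489 (permutation p = 1e-05 for each). Outside chromosome 10 the widest gains were on chromosome 22 from 29105703 to 29113731, chromosome 4 from 20621485 to 20629302, chromosome 2 from 86084741 to 86090973, chromosome 11 from 123100987 to 123107161 and chromosome 1 from 182268136 to 182274291. On chromosome 4 the IFN-γ libraries already had 4321 and 7817 bp in peaks, and the combination libraries had 1155 and 3262 bp. The widest losses were on chromosome 2 from 218702860 to 218718984 and from 119692569 to 119700090, on chromosome 22 from 46940757 to 46946760, on chromosome 1 from 23176238 to 23182082 and on chromosome 3 from 188616562 to 188622381. In the second of these, LPS alone gave 6153 and 7521 bp in peaks and the combination none.

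Priming gains numbered 1.86 times the 700 expected by chance (664 to 736) and losses 1.94 times the 489 expected (459 to 521), each with p = 1e-05 by the permutation test and 1e-05 after adjustment. Without regard to replicate number the expected counts were nearer to the observed ones, with 1125 gains and 714 losses (permutation p = 0.001 for each). Replicate 1 alone gave 5899 gains and 3971 losses and replicate 2 alone 20526 and 20124. The stronger 50% of each list gave 524 gains and 343 losses, and joining peaks gave 585 losses.

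IRF1 was mapped in 1 library per condition, so its differences have no replicate check and no p-value. Control cells had 226 IRF1 peaks covering 0.0647 Mb, IFN-γ 17594 covering 6.52 Mb, LPS 6990 covering 2.32 Mb, and the combination 7037 covering 2.15 Mb. Relative to control cells, 17398, 6794 and 6866 of the stimulated peaks were at positions without a control peak. Most LPS peaks had a counterpart after IFN-γ, 5513 of 6990 (78.9%, Wilson 95% interval 77.9 to 79.8), and so did 6074 of the 7037 combination peaks (86.3%, 85.5 to 87.1). In the other direction 5357 of the 17594 IFN-γ peaks (30.4%, 29.8 to 31.1) were found after LPS and 5931 (33.7%, 33.0 to 34.4) after both. These intervals cover counting error only. Of the 6990 LPS peaks, 4097 were shared with both other stimulated lists.

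Merged, the IRF1 lists formed 19609 regions. Of these, 10358 (52.8%) were found after IFN-γ only, 4062 (20.7%) in all 3 stimulated lists, with 158 of them also in control cells, 1071 (5.46%) after LPS only and 556 (2.84%) after the combination only. A further 1855 (9.46%) were found after IFN-γ and after the combination, 1263 (6.44%) after each signal alone and not after both, and 379 (1.93%) after LPS and after the combination. The IFN-γ list was the longest, with 17594 peaks against 6990 and 7037, so many of its peaks lack a counterpart by number alone. Of its 3519 peaks with the highest score, 76.0% were found after LPS and 87.3% after the combination. Of the 3519 with the lowest score, 7.90% and 6.08% were. With the lists shortened to the 6990 strongest peaks each, 6807 IFN-γ peaks had no control counterpart and 3425 LPS peaks were shared by all stimulated lists. When a shared peak had to overlap over 50% of both peaks, 2622 LPS peaks were shared by all stimulated lists.

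The strongest IRF1 peaks by the authors' score recurred from list to list. The position on chromosome 6 from 58777413 to 58778208 ranked first in the control, IFN-γ and LPS lists, and that on chromosome 1 from 121484994 to 121485152 ranked first in the combination list and second in the other lists. Of the 10 strongest in the IFN-γ list, only those on chromosome 6 from 58779218 to 58779389 and on chromosome 7 from 138796484 to 138797264 were absent from the control list. The latter was also found after LPS and after the combination, and 6 of the 8 H3K27ac libraries had a peak there. It was the exception: of the other 9, 8 overlapped no H3K27ac peak in any library, among them both top-ranked positions, and 1 did in 1 library. Of the 226 control peaks, 157 (69.5%) were found in all 3 stimulated lists. Whether positions that recur with and without stimulation reflect IRF1 binding was not tested, since no peak list of the input libraries was at hand.

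IRF1 was next related to acetylation, first by the share of IRF1 peaks that overlapped an H3K27ac peak; LPS lasted 6 hours in the IRF1 libraries and 3 hours in the H3K27ac libraries. Of the IFN-γ IRF1 peaks, 34.7% overlapped an H3K27ac peak of control cells and 44.9% one of IFN-γ-treated cells in replicate 1, and 59.3% and 80.9% did in replicate 2. Of the combination IRF1 peaks, 28.2% overlapped control and 54.6% combination H3K27ac peaks in replicate 1, and 56.2% and 83.8% in replicate 2. The share of IFN-γ IRF1 peaks within H3K27ac peaks was higher with than without IFN-γ by 14.2 points on average (7.24 to 21.6, higher in 4 of 4 pairs of libraries), and that of combination IRF1 peaks by 20.1 points (12.4 to 27.2, 4 of 4 pairs). Across the whole LPS list the share was higher with than without LPS by 7.49 points (0.0143 to 17.3, 4 of 4 pairs, of which the lowest rested on 1 IRF1 peak, 6001 against 6000, and turned to -0.0143 at the common score limit of -20), and higher with IFN-γ by 11.8 points (3.61 to 17.6, 4 of 4 pairs). For the combination list the LPS difference was 6.90 points (0.398 to 13.997, 4 of 4 pairs), and for the IFN-γ list -2.05 points (1 of 4 pairs higher). For IRF1 regions found after LPS only, the share was 27.7% in control cells and 56.9% after LPS in replicate 1, and 65.1% and 79.5% in replicate 2. The mean LPS difference there was 17.5 points (12.04 to 29.1, 4 of 4 pairs), and the IFN-γ difference was -2.96 points (2 of 4 pairs higher). For regions in all 3 stimulated lists the IFN-γ difference was 18.3 points (10.8 to 23.8, 4 of 4 pairs) and the LPS difference 5.90 (3 of 4). For regions found after IFN-γ only they were 11.1 points (4 of 4 pairs) and -5.86 (0 of 4), after the combination only 17.2 and 17.9 (4 of 4 each), in all 4 lists 2.69 (4 of 4) and 1.11 (1 of 4), and for the control list 1.33 (3 of 4) and -0.442 (1 of 4). Without chromosome 10 the IFN-γ differences for the IFN-γ and combination lists were 13.5 and 19.3 points, the LPS differences for the LPS and combination lists 8.41 and 7.77, the LPS difference for LPS-only regions 19.0, and the IFN-γ difference for regions in all 3 stimulated lists 17.3.

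None of these differences passed a test at 0.05. Exact permutation within replicate number could pass none of them, because its smallest p of 0.0556 lies above that threshold. Free permutation of all 8 libraries takes in the difference between replicate numbers as well. Permuting libraries within replicate number gave p = 0.0556, the smallest that this exact test allows, for the IFN-γ difference of the IFN-γ list, of the combination list and of the regions in all 3 stimulated lists, after IFN-γ only and in all 4 lists, and for the LPS difference of LPS-only regions, each 0.167 after Benjamini-Hochberg adjustment over 18 tests. Permuting all 8 libraries freely gave exact p = 0.286, 0.2, 0.2, 0.343, 0.171 and 0.229 for these. For the LPS list the exact p within replicate number was 0.222 for LPS (adjusted 0.364) and 0.111 for IFN-γ (adjusted 0.25), and for the LPS difference of the combination list it was 0.444 (adjusted 0.615). For the IFN-γ list it was 0.667 (adjusted 0.75), and for the IFN-γ difference of LPS-only regions 0.944 (adjusted 0.944). In the remaining 7 tests the exact p was 0.111 to 0.833 (adjusted 0.25 to 0.882).

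**Figure D3:**
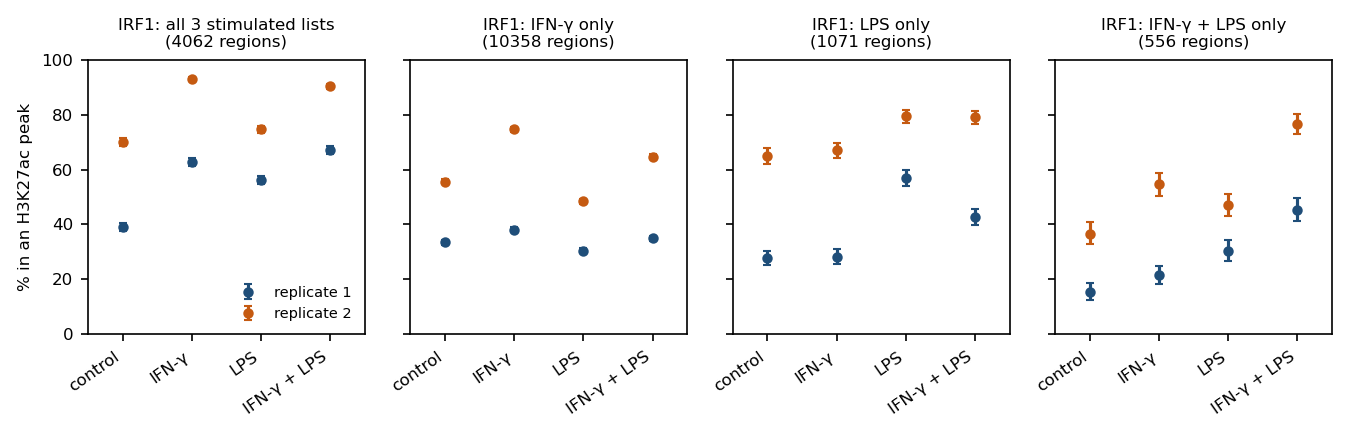
Percent of IRF1 regions that overlap an H3K27ac peak (vertical axis) in each H3K27ac library, by condition (horizontal axis), for IRF1 regions found in all 3 stimulated lists, after IFN-γ only, after LPS only and after the combination only; points are single libraries (blue replicate 1, orange replicate 2) with Wilson 95% intervals. In every panel all replicate 2 points stand above the replicate 1 point of the same condition, and in the LPS-only panel the replicate 1 share is 27.7% in control cells and 56.9% after LPS.

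The reverse view asked how many changed H3K27ac regions held an IRF1 peak. A gained or lost class fixes by definition where H3K27ac peaks are present or absent, and most IRF1 peaks of the stimulated lists lay in replicate 2 H3K27ac peaks of their own condition. Shares were therefore set against random union regions of like width, and also against random regions of like width and the same state, that is with or without an H3K27ac peak in each of the 2 libraries of the IRF1 list's condition. IRF1 was found at 509 of the 864 regions gained with IFN-γ (58.9%, Wilson 95% interval 55.6 to 62.1), against 26.3% (23.5 to 28.9) of regions of like width and 30.9% (28.1 to 33.7) of those in the same state. It was found at 9 of the 612 regions lost with IFN-γ (1.47%, 0.776 to 2.77), below the 15.8% (13.4 to 18.6) of regions of like width but within the range of those in the same state (1.31%, 0.490 to 2.29). Of the regions gained with both signals, 758 of 2915 (26.0%, 24.4 to 27.6) had an IRF1 peak of the combination list, against 9.78% (8.82 to 10.8) by width and 11.9% (10.9 to 12.97) in the same state. Among the 1545 lost regions 11 did (0.712%, against 8.74% by width and 1.36% in the same state, 0.906 to 1.81). Regions gained by priming in LPS-stimulated cells had a combination IRF1 peak in 349 of 1300 cases (26.8%, against 8.31% and 10.3%), and those lost in 5 of 949 (0.527%, against 6.11% by width and within the range in the same state, 0.527 to 1.69). Of these 1300 gains, 187 lay on chromosome 10, and their share without that chromosome is not given.

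Shares at LPS gains were nearer to those of random regions. Of the 1986 regions gained with LPS alone, 306 (15.4%, 13.9 to 17.1) had a peak of the LPS IRF1 list, against 8.46% (7.35 to 9.62) by width and 9.67% (8.51 to 10.8) in the same state. A peak of the IFN-γ list was found in 11.98% of them, below the 18.4% by width and above the 9.11% (8.11 to 10.2) in the same state. Among the 1068 LPS losses 21 had a peak of the LPS list (1.97%, against 7.58% by width and 4.78% in the same state). Without chromosome 10 the share at LPS losses was 1.45%. Regions gained with LPS in primed cells had a combination IRF1 peak in 113 of 1348 cases (8.38%, 7.02 to 9.98), within the range by width (6.08 to 8.75) and in the same state (7.86 to 10.8). A peak of the IFN-γ list was found in 2.52% of them, against 16.8% by width and 1.41% (0.890 to 2.003) in the same state. Of the 349 regions lost with LPS in primed cells 13 had a combination peak (3.72%), below the 8.31% by width and above the 1.15% (0.287 to 2.58) in the same state. The 409 regions acetylated under the combination only had one in 37 cases (9.05%, against 4.65% by width and 6.11% in the same state, 3.91 to 8.31). At the 14100 regions acetylated in all 8 libraries the share was 14.3%, against 16.0% and 18.9%.

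These percentages set regions against random sets of regions, 10000 for each class, and describe these libraries only. They moved with the replicate used. With replicate 1 alone and with replicate 2 alone, IFN-γ gains had an IFN-γ IRF1 peak in 36.1% and 18.5% of cases, against 22.4% and 7.14% of random regions of like width drawn for each, and IFN-γ losses in 13.5% and 0.357%, against 22.7% and 4.78%. Combination gains had a combination peak in 19.5% and 6.49%, against 9.57% and 2.84%, and LPS gains a peak of the LPS list in 17.5% and 3.39%, against 10.1% and 2.41%. For regions gained with LPS in primed cells the side turned, with a combination peak in 12.7% and 1.43%, against 8.24% and 2.08%. The random regions for 1 replicate matched on width only and not on state. The side on which a class falls is thus partly set by its definition. IFN-γ losses, for instance, have no H3K27ac peak in the IFN-γ library used. With the stronger 50% of the IRF1 peaks, the share was 51.3% for IFN-γ gains, 16.9% for combination gains and 9.21% for LPS gains.

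**Figure D4:**
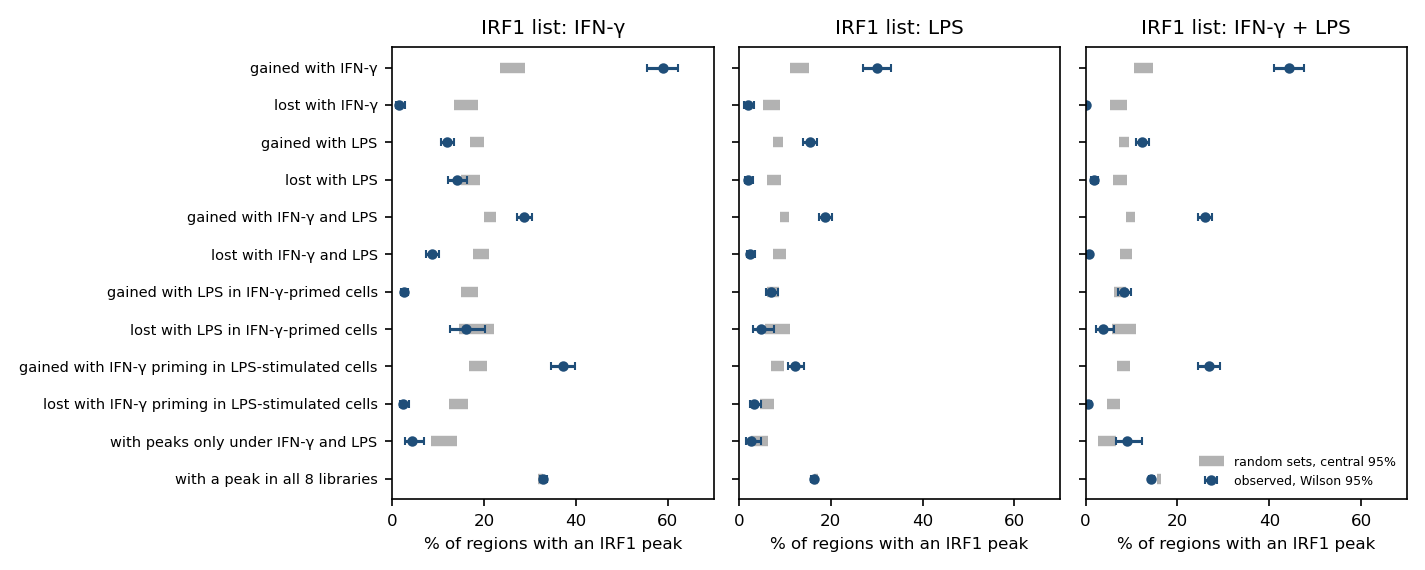
Percent of H3K27ac regions of each class (rows of the plot) with an IRF1 peak of the IFN-γ, LPS or combination list (left to right); points with whiskers are the observed percent with its Wilson 95% interval, and grey bars the central 95% of 10000 random sets of union regions of like width. Regions gained with IFN-γ stand furthest to the right of their random sets in the IFN-γ panel, at 58.9% against 23.5 to 28.9%. The grey bars match on width only, so the place of a class without H3K27ac peaks in the IRF1 list's condition, such as regions lost with IFN-γ at 1.47%, is partly set by its definition.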

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

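Of the tests given here, the search for misplaced positions on chromosome 10 and the check of chromosome 10 in the replicate 1 lists were chosen only after the result was seen, and the 500 bp distance and the omission of chromosome 10 were added after the data were seen.

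The number of IRF1 peaks moved in opposite directions with LPS depending on priming. Without IFN-γ, LPS raised it by 4.95 on the log2 scale, from 226 to 6990 peaks, and with IFN-γ the change was -1.32, from 17594 to 7037, so the effects differ by -6.27, a difference between single libraries that was not tested. A weaker library in the combination is a candidate explanation: of the IFN-γ peaks, 6.08% of the 3519 with the lowest score and 87.3% of the 3519 with the highest were found again, as a higher effective limit would give. In the LPS list recovery of the same peaks climbed as well, from 7.90% to 76.0%. The climb is thus no sign of a weaker combination library in particular. A loss of IRF1 at weak sites would look alike, so the climb does not exclude a biological decrease. Whether IRF1 moved to sites that LPS acetylates stays open. In regions gained with LPS in primed cells lay 8.62% of the 963 combination peaks absent after IFN-γ and 0.103% of the IFN-γ peaks not found again, but these regions have by definition no H3K27ac peak after IFN-γ, which lowers the latter share in any case, and the share of these regions with a combination IRF1 peak, 8.38%, was within the range of random regions of like width (6.08 to 8.75).

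At the 1071 IRF1 regions found after LPS only, IFN-γ went with opposite changes in the share that overlapped an H3K27ac peak. Without LPS the share was higher with IFN-γ by 1.26 points on average and with LPS the difference was -7.19 points, so the effects differ by -8.45 points, and the difference was not tested. Both replicates were on the same side each time, but the size rested on replicate 1: without LPS the differences were 0.467 points in replicate 1 and 2.05 in replicate 2, and with LPS -14.1 and -0.28. The sides without LPS changed under alternatives. Within 500 bp the replicate 2 share was 76.8% without and 75.4% with IFN-γ, and at equal list lengths the replicate 1 share was 27.7% and 27.4%. Without chromosome 10 the replicate 2 share in LPS-stimulated cells was 84.2% without and 79.5% with IFN-γ.

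The replicate 2 LPS list of H3K27ac has 961 peaks on chromosome 10, all within its first 3.81 Mb. Positions that are wrong as a whole are argued against by the 84 control replicate 2 peaks in this stretch, of which 98.8% were found in the list, against 24.9% at random positions in it. Removal of acetylation along the chromosome by LPS is argued against by replicate 1, where chromosome 10 held 4.36% of the LPS list and at least 4.44% of the others. A list that holds only the first part of the chromosome may explain why no peak lies beyond it, but the share found does not decide this. The 98.8% lies above the 62.9% found on the other chromosomes. The list holds 961 peaks where control replicate 2 has 84, and so many peaks raise the share found in any case. What stays open is why the stretch also holds 894 peaks seen in no other list, with a median height of 17 against 61 for the other 67.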

How the results depend on the processing

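The common score limit of -20, the 500 bp distance between IRF1 and H3K27ac and the omission of chromosome 10 were added after the data were seen. The 11 counts of changed regions exceeded chance under every alternative that gives a test, with 1 exception: with no replicate block, losses with LPS in primed cells numbered 349 against 602 by chance (permutation p = 1). Without the block the other 10 counts kept a permutation p of 0.001, the smallest that its 1000 draws can give, with chance means from 188 to 1159.8. The labels do not say that the replicate numbers pair the libraries. Deviations of same-numbered libraries from their condition means correlated by 0.0129 to 0.286, above 0.1 in 5 of 6 pairs of conditions, and lists of one number shared more base pairs (Jaccard index 0.464 to 0.635) than lists of different numbers (0.285 to 0.416), a hint from the data and not the design. With the replicate block the factor differences, -0.01 and 0.09 for peak number and 0.11 and 0.06 for covered length (IFN-γ, then LPS), had exact permutation p = 0.889, 0.389, 0.278 and 0.667, and the block changed no other call. The agreement of conditions between replicates was 0.0879 to 0.272 under the alternatives, above all other matchings each time (exact permutation p = 0.0417). Without chromosome 10 all 27 recomputed results had the same direction and side of the threshold. The 27 at the common limit of -20 did too, and there the combination IRF1 share of combination gains rose from 26.0% to 28.2%, beyond its interval. Unknown depth limits all of this, since a peak missing from a list can be a weak one. The alternatives for gene windows, gene backgrounds and motifs were not run, for want of an annotation or genome of the build used. The causes of the moves listed next were not tested, except that lists cut to 50% hold fewer peaks by construction.

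The stronger 50% of each list gave gains of 396, 835, 1311, 533 and 524 and losses of 238, 453, 619, 177 and 343 for IFN-γ, LPS, both, LPS in primed cells and priming, 131 regions with the combination only, 8705, 3398 and 3431 IRF1 peaks absent from control cells after IFN-γ, LPS and both, and 2131 shared LPS peaks. Equal list lengths gave 1524 gains and 1155 losses with IFN-γ, and 1945, 2427 and 821 losses with LPS, both, and LPS in primed cells. Peaks covering 50% of a region gave 429 IFN-γ gains. Peaks joined over 500 bp gave 1285 gains and 691 losses with LPS, 399 losses with IFN-γ, 818 gains with LPS in primed cells, 585 losses with priming, and 223 regions with the combination only. Reciprocal overlap gave 2622 shared IRF1 peaks, and equal IRF1 lists 6807 IFN-γ peaks absent from control cells. The stronger 50% of the IRF1 lists gave shares of 51.3% and 0.327% for gains and losses with IFN-γ, 9.21% and 0.749% with LPS, 16.9% and 0.324% with both, and 5.13% with the combination only. The direction turned for the LPS difference in covered length on the untransformed scale (-0.535 Mb; exact permutation p = 0.971) and for the IFN-γ difference in peak number among wide peaks (log2 0.0615; exact permutation p = 0.686).

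With 1 replicate left out, gains ranged from 5689 to 17262 with IFN-γ, 6985 to 19675 with LPS, 9184 to 23571 with both, 6238 to 18588 with LPS in primed cells and 5899 to 20526 with priming. Losses ranged from 3467 to 26024, 3911 to 28205, 4182 to 31699, 3458 to 17954 and 3971 to 20124 in the same order, and regions with the combination only from 3495 to 10748. The IRF1 share ranged from 18.5% to 36.1% and 0.357% to 13.5% for gains and losses with IFN-γ, 3.39% to 17.5% and 1.13% to 5.96% with LPS, 6.49% to 19.5% and 0.227% to 3.54% with both, and 1.32% to 12.4% with the combination only. The log2 difference in peak number ranged from -0.17 to 0.14 for IFN-γ and from -0.0088 to 0.19 for LPS, and in covered length from 0.11 to 0.12 for IFN-γ and from -0.12 to 0.24 for LPS. A change seen in 1 library has fewer conditions to meet, which raises these counts by construction.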

Other observations

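The windows of 100 kb, the counts of recurrent control peaks and the pattern weighed last were chosen after the lists had been seen; the tests of that pattern were set before their own results, except the use of replicate 2 in the test of gaps and of equal peak numbers in the test of coverage, which were chosen after their values were seen.

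Changed regions lay close together in places. On chromosome 2 between 242.7 and 242.8 Mb, 14 of 32 union regions were gained with the combination, the same number with LPS in primed cells and 11 with priming in LPS-stimulated cells, and 11 had peaks in the combination libraries only. On chromosome 18 between 21.4 and 21.5 Mb, 12 of 36 regions were gained with the combination and 8 had peaks under the combination only. LPS gains were most numerous on chromosome X between 43.8 and 43.9 Mb, where 15 of 44 regions were gained with LPS and 9 were lost when primed cells were compared with LPS alone, and on chromosome 2 between 145.1 and 145.2 Mb, with 10 of 56 gained and 9 lost. IFN-γ gains were most numerous on chromosome 16 between 11.3 and 11.4 Mb, with 5 of 29 regions and 8 IRF1 peaks of the IFN-γ list. Losses with the combination were most numerous on chromosome 2 between 216.5 and 216.6 Mb, with 11 of 48 regions, and the IFN-γ comparison gave 7 losses in the same window. No test was made of these windows.

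IRF1 peaks of the stimulated lists also crowded in windows. After IFN-γ the highest count was 13, on chromosome 5 from 43 to 43.1 and from 169.7 to 169.8 Mb. After LPS it was also 13, on chromosome 2 from 133 to 133.1 Mb, a window that ranked first in the control list as well, with 15 peaks. Next after LPS were 12 on chromosome 17 from 76.3 to 76.4 Mb, 11 on chromosome 2 from 113.5 to 113.6 Mb, and 10 in each of the neighbouring windows of chromosome 6 from 138 to 138.1 and from 138.1 to 138.2 Mb. After the combination 10 lay on chromosome 5 from 40.4 to 40.5 Mb, and windows with 9 included chromosome 16 from 11.4 to 11.5 Mb and again chromosome 6 from 138.1 to 138.2 Mb.

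The 157 control IRF1 peaks found in all 3 stimulated lists lay closer together than peaks of the IFN-γ list. Of these, 28.0% lay within 10 kb of another, while the 95th percentile of random draws from the IFN-γ list was 2.55%. An H3K27ac peak of control cells overlapped 47.8% of them in replicate 1 and 55.4% in replicate 2, against 34.5% and 59.4% of the other IFN-γ peaks, a difference that went opposite ways in the replicates and was not tested. A peak was present at 71 of them in all 8 H3K27ac libraries and at 64 in none. That these recurrent positions are sites of IRF1 binding was not tested.

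IFN-γ IRF1 peaks fell outside the IFN-γ H3K27ac peaks of replicate 1 more often than those of replicate 2, with 44.9% and 80.9% inside. Gaps between closely spaced acetylated stretches, taken as an H3K27ac peak within 500 bp on each side, held few of the outside peaks. They held 383 of the 9702 IRF1 peaks outside replicate 1 peaks (3.95%) and 193 of the 3365 outside replicate 2 peaks (5.74%). Such gaps can therefore account for little of this difference. Both shares exceeded positions shifted by 5 to 50 kb (0.203% and 0.586%), so the prediction that IRF1 peaks lie in gaps more often than shifted positions was met. Proximity to acetylated stretches on any side stays open as an account of where the outside peaks lie. An H3K27ac peak lay within 500 bp of 1687 of the 9702 and of 836 of the 3365. Of these, 22.7% in replicate 1 and 23.1% in replicate 2 had one on both sides, against 6.996% and 10.4% of shifted positions. The prediction for proximity alone, a share no higher than at shifted positions, was not met. A peak on both sides is itself proximity, however, and the test leaves out the peaks with none within 500 bp, so it does not decide. Whether smaller coverage of the genome by the replicate 1 list is the cause stays open, since the way of matching the lists sets the order. The strongest replicate 2 peaks covering as many base pairs held 32.9% of the IRF1 peaks, less than the 44.9% of replicate 1, but numbered 8991 against 36149, while with 32253 peaks each replicate 2 held 72.4% and replicate 1 43.2%.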
